A study of Homo sapiens with 6 samples.

How the data were processed

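Transcript levels were taken from a single deposited table with 1 column per library for 6 RNA-seq libraries of MDA-MB-231 cells, 3 from non-treated controls and 3 from cells given 40 µM of ArA for 24 h. Per the labels' protocols, cells grew in DMEM with 10% fetal bovine serum at 37°C and 5% CO2, and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The labels do not name a vehicle for the control cells. Groups and replicate numbers came from the sample titles, and each column was matched to its sample by name.

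The authors deposited values in TPM, which divide reads by transcript length and scale each library to the same total. Every column summed to the same total within rounding over all lines of the table. HISAT2, StringTie, RSEM and the genome build hg38 are named in the submitters' processing notes, without versions. The part each tool played, the gene annotation and whether counting used strand are not given in the sources used here. TPM holds no read counts, so depth per library is unknown, no counting interval can be given, and a low gene's precision is known only from the spread between replicates. As TPM are shares, a fall in abundant transcripts raises all others, and mitochondrially encoded transcripts took 26.9 to 32.9% of the total. An exact 0 in such a table can be a failed estimate, so genes at 0 are given as listed values.

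The table held 63241 genes and 50 lines that name no gene, 25 of them blank and 25 with annotation text, which were left out. Of the 63241 genes, 28138 were above 0 in at least 1 library. Genes with a mean of at least 1 TPM over the 6 libraries were tested (12999 genes, 765 of them without a symbol). Levels were put on the log2(TPM + 1) scale, with a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with group as the only term. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. Fold differences are ratios of mean TPM. SRM also had an exact permutation test of its 6 values. Genes were called separated where all 3 ArA values lay on the same side of all 3 control values.

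A set of 27 gene lists was fixed before the data were examined, together with the tests, the main design, the processing alternatives and a rule for naming genes. The lists cover lipid handling and beta-oxidation, fatty acid synthesis, cholesterol synthesis, eicosanoids, polyamines, NRF2, ferroptosis, ATF4, ER chaperones, heat shock, NF-kB, interferon, immediate early genes, G2/M, DNA replication, p53, hypoxia, oxidative phosphorylation, extracellular matrix, vesicle secretion, MYC, ribosomal proteins, mitochondrially encoded transcripts, histones and markers of luminal, blood, and fibroblast or muscle cells. Of 712 distinct genes in the lists, 700 were found in the table. Some genes stand in several lists, such as ANGPTL4 in lipid handling and hypoxia, VLDLR in lipid handling and ATF4, and FTH1 in NRF2 and ferroptosis. Lists were tested against all other genes with camera at the preset correlation of 0.01, adjusted over the 27 lists, then with camera at an estimated correlation and with fry. List members were also adjusted over the list alone.

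The naming rule took SRM, up to 8 genes per direction with the largest log2 fold change past the threshold with a mean of at least 5 TPM in the higher group and separated groups, and up to 2 members per direction of each list with members past the threshold. Only SRM, ANGPTL4, PLIN2 and IGF2BP2-AS1 met these parts. The rule also allowed the member with the highest mean TPM of each list with none past the threshold, but no gene was chosen by that part. All other genes named were chosen after their values had been seen, as the members with the smallest p, the highest rank among all genes or a known role in the list, and they do not stand as independent tests.

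Coordinates, GC content and transcript length came from GENCODE v29 on hg38, matched by Ensembl gene identifier, using the longest transcript of each gene. Of the tested genes, 12637 (97.2%) had a GC value. After libraries were seen to differ by GC content, a GC correction was added: each library's deviation from the gene mean was fitted on GC content with a natural spline of 5 degrees of freedom, and the fitted trend was subtracted.

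The alternatives fixed together with the lists were 3 other scalings (median of ratios, quantile normalization and TPM rescaled without mitochondrially encoded genes), pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 TPM, the replicate number as a block, eBayes without trend, robust eBayes, array weights, a log2 fold change of at least 1 in size, and each library left out in turn. Alternatives chosen after seeing the data were the GC correction, alone, with the replicate block and with an estimated correlation, a term for control replicate 2 and ArA replicate 1 against the other 4 libraries, and a fit without these 2.

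The procedure was tested on simulated data for ArA versus control: 20 simulations over 12999 genes with 200 changed genes each. Recovery was 10.6% of genes changed by 0.5 on the log2 scale, 68.1% at 1 and 90.5% at 1.5, with 6.35 false calls per simulation. With 200 changed genes the adjusted threshold is easier to pass than in the real data, where 3 genes passed. The simulated noise was also independent between genes and held no library pair. These rates can therefore overstate recovery in the real data. For lists of 30 genes shifted by 0.2 on the log2 scale, camera found 20 of 20 and called 0 of 520 unshifted lists, with simulated genes independent of each other. Among the lists past camera in the real data, the estimated correlation ranged from -0.0410 for histones to 0.616 for mitochondrially encoded transcripts. It was 0.324 for G2/M. The simulation does not show how often camera calls unshifted lists of correlated genes. On a simulated GC trend over 12637 genes, the correction took the rank correlation from 0.859 to 0.00364. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.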

Results

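RNA was measured in MDA-MB-231, a human triple-negative breast cancer cell line of mesenchymal character. Of 6 libraries, 3 came from cells given 40 µM of ArA and kept for 24 h, and 3 from non-treated control cells. The study's title spells the name behind ArA as arachidonic acid, a polyunsaturated fatty acid of membrane lipids from which prostaglandins and other eicosanoids are made. Each library is described by values in TPM, the abundance of a gene's transcripts as a share of all transcripts in the library, for 63241 genes, of which 28138 were above 0 in at least 1 library and 12999 had a mean of at least 1 TPM and were tested. TPM keeps no read totals, so the depth of each library is unknown. The labels do not say whether replicates came from separate cultures, and the p-values measure only the spread between these libraries, which may be technical.

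The comparison of ArA-treated with control cells asks which transcripts differ after exposure to the fatty acid. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 19.0 ± 1.33 TPM in control libraries to 60.7 ± 4.82 TPM in ArA libraries (SD, n = 3 each), a 3.20-fold difference of means. PLIN2, which coats lipid droplets, rose from 77.5 ± 1.98 to 147 ± 8.45 TPM (SD, n = 3 each), or 1.89-fold. IGF2BP2-AS1, a transcript antisense to IGF2BP2, fell: it was listed at 5.15, 5.68 and 5.15 TPM in control replicates 1, 2 and 3 and at 0.05, 0 and 0 TPM in ArA replicates 1, 2 and 3. In the limma fit on log2(TPM + 1), a scale that understates the change of low genes, the log2 fold change was 1.63 (SE 0.10, adjusted p = 0.00538) for ANGPTL4 and 0.91 (SE 0.08, adjusted p = 0.0331) for PLIN2. For IGF2BP2-AS1 the adjusted p was 0.00431. These were the only 3 of 12999 genes past an adjusted p of 0.05, 2 higher and 1 lower, and each separated the 3 ArA libraries from the 3 control libraries. At an unadjusted p under 0.05 there were 362 genes, 296 higher and 66 lower, which is 2.79% of those tested. That lies below the share of 0.05 that no difference would give on average. All 6 libraries were separated by group for 1046 genes, or 8.05% of those tested, where chance gives 10% for 3 against 3. No gene passed without control replicate 1 or without ArA replicate 2, where 413 and 228 genes had an unadjusted p under 0.05 in limma. After scaling by median of ratios, 1 higher and 1 lower gene passed, and the genes with an unadjusted p under 0.05 split into 154 higher and 108 lower.

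ANGPTL4 (ENSG00000167772) lies on the forward strand of chromosome 19 from 8363289 to 8374373, and PLIN2 (ENSG00000147872) on the reverse strand of chromosome 9 from 19108375 to 19149290, both protein-coding genes in GENCODE v29 on hg38. IGF2BP2-AS1 (ENSG00000163915) lies on the forward strand of chromosome 3 from 185712528 to 185729787, inside the span of IGF2BP2 on the reverse strand from 185643739 to 185825056. The sources used here do not say whether counting used strand, so reads from IGF2BP2-AS1 and IGF2BP2 may not be separated, and its level is uncertain. IGF2BP2 itself, which codes for an RNA-binding protein, had 15.52, 7.93 and 13.95 TPM in the control libraries and 13.41, 21.77 and 15.06 TPM in the ArA libraries. The next gene by p was AQP3, a water and glycerol channel, at 79.6 ± 6.66 TPM in control and 154 ± 12.4 TPM in ArA libraries (SD, n = 3 each), with an adjusted p of 0.0909 in limma. FABP4, an intracellular fatty acid carrier, had 3.18 ± 0.883 TPM in control and 13.1 ± 3.64 TPM in ArA libraries, a log2 fold change of 1.75 (SE 0.25, adjusted p = 0.335). AQP3 and FABP4 both passed once the libraries' trends with GC content had been removed, at adjusted p = 0.0353 and 0.00207. Over all alternatives the adjusted p ranged from 0.000659 to 0.812 for AQP3 and from 0.00207 to 1 for FABP4.

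**Figure D1:**
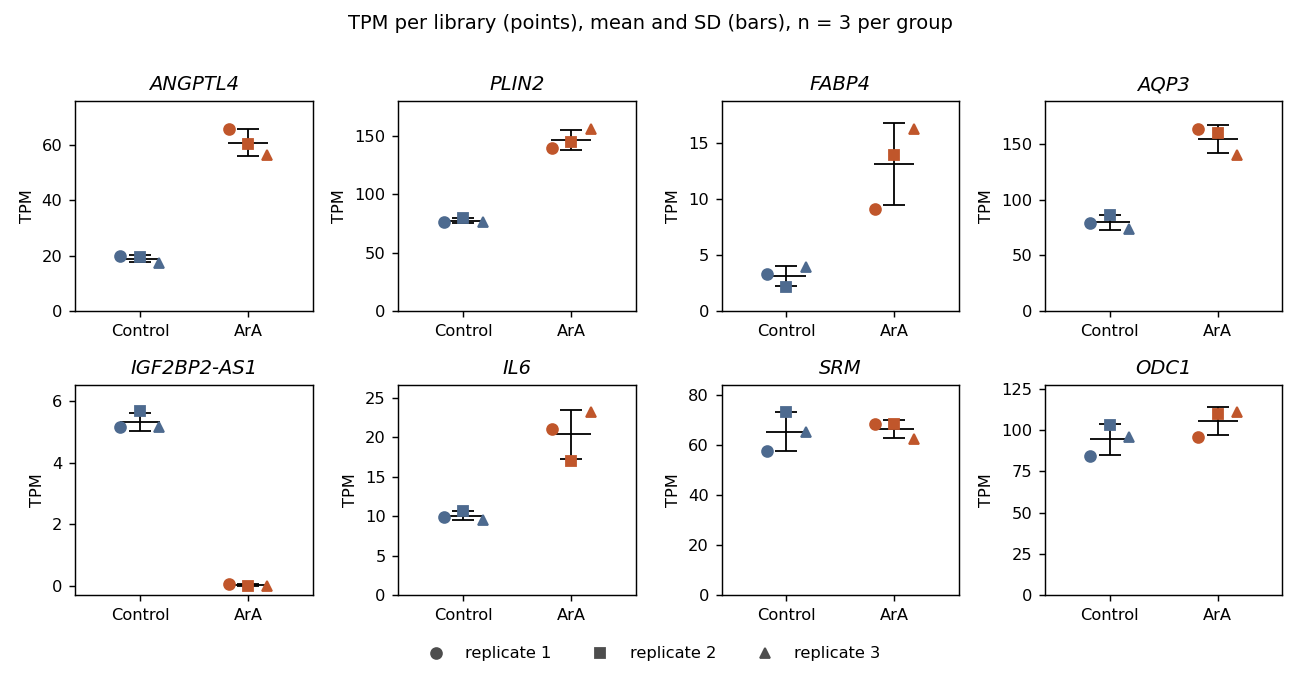
TPM (vertical axes, each starting at 0 except that of IGF2BP2-AS1, which starts just below it) of 8 genes in control and ArA libraries; points are single libraries, with the marker giving the replicate number, and bars are the mean and SD of 3 libraries. ANGPTL4, PLIN2 and IGF2BP2-AS1 passed the limma test, FABP4, AQP3, IL6, SRM and ODC1 did not, and the means of SRM were 65.3 TPM in control and 66.4 TPM in ArA libraries.

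The study's title names spermidine synthase, the enzyme that makes spermidine from putrescine and is encoded by SRM (ENSG00000116649), on the reverse strand of chromosome 1 from 11054584 to 11060024. SRM had 65.3 ± 7.82 TPM in control and 66.4 ± 3.47 TPM in ArA libraries (SD, n = 3 each). The log2 fold change was 0.03 (SE 0.11, 95% interval -0.23 to 0.29, limma adjusted p = 0.999), which bounds the fold between 0.854 and 1.22. The exact 2-sided permutation test gave p = 0.8, where the smallest p that 3 against 3 libraries allow is 0.1. The sign of this difference turned negative, at -0.02 to -0.03, under each of the 3 other scalings and after GC correction. In the main analysis SRM already lay below the median log2 fold change of all tested genes, which was 0.06. Of 18 tested genes of polyamine metabolism, 0 passed over all genes and 0 adjusted over the list alone, and 14 had positive log2 fold changes under the main scaling. ODC1, the first enzyme of polyamine synthesis, had 94.4 ± 9.32 TPM in control and 105 ± 8.47 TPM in ArA libraries, spermine synthase SMS had 108 ± 13.0 and 105 ± 14.1 TPM, and spermine oxidase SMOX had 4.37 ± 0.240 and 4.93 ± 0.946 TPM (SD, n = 3 each). The list's camera adjusted p was 0.787. Its median log2 fold change was 0.05 and became -0.01 when TPM were rescaled without mitochondrially encoded genes.

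Genes of lipid handling and fatty acid oxidation that respond to PPAR receptors were higher as a group in ArA libraries at the preset correlation. Of 30 tested members, 26 had positive log2 fold changes (23 under each other scaling), 14 were higher in all 3 ArA libraries than in all 3 control libraries, and the median was 0.19. ANGPTL4 and PLIN2 rose over all genes, and 9 members rose adjusted over the list alone: these 2 with FABP4, ECH1, VLDLR, CPT1A, SLC25A20, ACAA2 and CREB3L3. CPT1A, the gatekeeper of mitochondrial fatty acid import, had 42.2 ± 2.49 TPM in control and 54.9 ± 3.35 TPM in ArA libraries, and ECH1, an auxiliary enzyme of beta-oxidation, had 97.4 ± 1.25 and 132 ± 7.80 TPM (SD, n = 3 each). The carnitine carrier SLC25A20 had 21.3 ± 1.02 and 27.5 ± 1.71 TPM, and the lipoprotein receptor VLDLR 20.2 ± 1.32 and 27.5 ± 2.11 TPM. The thiolase ACAA2 had 33.8 ± 0.942 and 43.2 ± 3.89 TPM, and CREB3L3, a low-level transcription factor gene, 0.680 ± 0.149 and 1.53 ± 0.291 TPM. The camera adjusted p of the list was 4.6e-12 with the preset correlation, and adjusted p = 0.122 with an estimated correlation.

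Of the stress-response lists, NRF2, ferroptosis, ATF4 and ER chaperones were higher as groups in ArA libraries at the preset correlation. The heat shock list did not pass camera (adjusted p = 0.957). All 24 tested members of the NRF2 oxidative stress list had positive log2 fold changes under the main scaling and 23 under each other scaling, with a median of 0.21, and 12 separated the groups; 0 passed over all genes and 0 adjusted over the list alone. The quinone reductase NQO1 had 376 ± 16.7 TPM in control and 464 ± 16.1 TPM in ArA libraries, and ferritin heavy chain FTH1 had 1305 ± 105 and 1675 ± 95.2 TPM (SD, n = 3 each). Heme oxygenase HMOX1 had 21.3 ± 3.59 and 28.7 ± 3.64 TPM, and GCLC, which makes the first product of glutathione synthesis, 11.2 ± 1.58 and 15.2 ± 2.33 TPM. The NRF2 list's camera adjusted p was 6.2e-12, and adjusted p = 0.122 with an estimated correlation. Its median was 0.32 without ArA replicate 1, or 0.21 less the median of all genes, against 0.15 with all libraries. The ferroptosis and lipid peroxidation list, which shares FTH1, had 20 of 22 members positive (12 or 13 under the other scalings), with a camera adjusted p of 0.00492 and adjusted p = 0.245 with an estimated correlation. Its member LPCAT3, which places polyunsaturated fatty acids into phospholipids, had 63.0 ± 5.76 and 81.2 ± 6.17 TPM. Of 30 members of the ATF4 integrated stress response list, 29 were positive (22 or 23 under the other scalings), among them the transcription factor CEBPB at 33.4 ± 2.41 and 42.7 ± 1.20 TPM and asparagine synthetase ASNS at 56.5 ± 1.12 and 65.1 ± 0.402 TPM. The ATF4 list's camera adjusted p was 0.000495, and adjusted p = 0.289 with an estimated correlation. All 24 ER chaperone and unfolded protein response genes were positive under the main scaling (23 under quantile normalization), by 0.07 to 0.21 on the log2 scale, with PDIA4 at 295 ± 31.0 and 340 ± 8.50 TPM and HSPA5 at 642 ± 75.3 and 720 ± 33.5 TPM. Their camera adjusted p was 6.7e-05, and adjusted p = 0.307 with an estimated correlation. In the ferroptosis, ATF4 and ER lists, 0 members passed over all genes and 0 adjusted over the list alone.

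Interferon-stimulated and inflammatory genes were higher as groups in camera at the preset correlation only. Of 29 interferon-stimulated genes, 28 had positive log2 fold changes under the main scaling and at least 26 under each other scaling, 11 separated the groups, and the median was 0.19. OASL, an antiviral protein gene, rose adjusted over the list alone, from 71.7 ± 2.78 to 105 ± 10.2 TPM (SD, n = 3 each), with 0 members past over all genes. MX2, IFITM1 and OAS1, also antiviral, had 19.2 ± 2.42, 197 ± 25.7 and 104 ± 4.11 TPM in control and 27.8 ± 2.09, 286 ± 41.3 and 132 ± 12.9 TPM in ArA libraries. The interferon list's camera adjusted p was 7.3e-09, and adjusted p = 0.253 with an estimated correlation. Its median was 0.11 without ArA replicate 3 (24 members positive), 0.34 without ArA replicate 1, 0.35 without control replicate 1 and 0.29 without control replicate 3, and 21 members were positive without control replicate 2. Less the median of all genes, these 4 medians were 0.09, 0.22, 0.27 and 0.20, against 0.14 with all libraries. Among 24 NF-kB target and cytokine genes, 18 were positive; 0 passed over all genes, and IL6 and IL1B rose adjusted over the list alone. The cytokine IL6 had 10.0 ± 0.582 TPM in control and 20.4 ± 3.11 TPM in ArA libraries, a log2 fold change of 0.94 (SE 0.14), while IL1B had 3.07 ± 0.232 and 6.41 ± 1.90 TPM and CSF2 8.18 ± 1.84 and 11.6 ± 0.483 TPM. This list's camera adjusted p was 0.0107, and adjusted p = 0.307 with an estimated correlation. Of 25 immediate early genes, 21 were positive (17 or 18 under the other scalings); JUN, part of the AP-1 factor, rose adjusted over the list alone, from 37.5 ± 2.13 to 50.5 ± 0.836 TPM, with 0 past over all genes. The phosphatase gene DUSP1 had 25.6 ± 2.89 and 32.8 ± 1.74 TPM. The immediate early list's camera adjusted p was 0.00984, and adjusted p = 0.342 with an estimated correlation; the call was lost under quantile normalization (adjusted p = 0.0639, 17 members positive) and without control replicate 1 (adjusted p = 0.226). In eicosanoid metabolism, 13 of 16 members were positive and the camera adjusted p was 0.0562, a call that depended on the setting, since the list passed in 9 of 23 alternatives, with adjusted p from 0.0110 to 0.497; PTGES, the inducible prostaglandin E synthase, rose adjusted over the list alone, from 11.8 ± 1.43 to 19.3 ± 1.21 TPM, with 0 past over all genes.

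Extracellular matrix and hypoxia genes were also higher as groups under the main scaling with the preset correlation. Of 31 extracellular matrix and mesenchymal genes, 25 were positive (20 or 21 under the other scalings) and 0 passed over all genes or adjusted over the list alone. THBS1 had 56.4 ± 7.02 TPM in control and 72.0 ± 0.671 TPM in ArA libraries, while the collagenase MMP1 had 13.2 ± 1.13 and 11.1 ± 0.630 TPM (SD, n = 3 each). The matrix list's camera adjusted p was 0.00407, and adjusted p = 0.458 with an estimated correlation. The call was lost with median-of-ratios scaling (adjusted p = 0.0559, 21 members positive) and without control replicate 3 (adjusted p = 0.735). Less the median of all genes, the matrix list's median was 0.0591 in the main analysis. It was 0.0537 with median-of-ratios scaling and 0.00254 without control replicate 3. Of 30 hypoxia and glycolysis genes, 27 were positive under the main scaling and 16 to 20 under the others, with a median of 0.07 against 0.01 to 0.03. Less the median of all genes, which differs between scalings, the list's median was 0.0177 against 0.0127 to 0.0245. Only ANGPTL4, which this list shares with the lipid list, rose, both over all genes and adjusted over the list alone. The hypoxia list's camera adjusted p was 0.0110, and adjusted p = 0.253 with an estimated correlation; the call was lost under each of the 3 other scalings, at adjusted p from 0.0530 to 0.0954, and without control replicate 1 (adjusted p = 0.384). Without ArA replicate 1 the matrix, hypoxia, NF-kB, immediate early and DNA replication lists no longer passed, at camera adjusted p = 0.880, 0.146, 0.241, 0.0843 and 0.105.

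Cell division genes were lower as a group in ArA libraries in camera at the preset correlation. All 30 genes of the G2/M list had negative log2 fold changes under each of the 4 scalings, with a median of -0.11 under the main scaling, but only 3 separated the groups, and 0 passed over all genes or adjusted over the list alone. Those 3 were the phosphatase gene CDC25C, at 18.7 ± 1.30 TPM in control and 16.4 ± 1.16 TPM in ArA libraries, the spindle gene TPX2, at 131 ± 5.14 and 122 ± 4.56 TPM, and cyclin B1 gene CCNB1, at 190 ± 7.15 and 178 ± 2.85 TPM (SD, n = 3 each). The G2/M list's camera adjusted p was 3.9e-10, and adjusted p = 0.277 with an estimated correlation. Less the median of all genes, the list's median was -0.17, and -0.16 without ArA replicate 1, -0.13 without control replicate 3, -0.29 without control replicate 2 and -0.21 without ArA replicate 3. Without ArA replicate 1 the median of all genes was 0.12, against 0.06 with all libraries, and 13 of the 30 members had positive log2 fold changes, with a list median of -0.04. The list median itself was -0.04, -0.28 and -0.19 without the other 3 libraries named. Of 30 DNA replication and G1/S genes, 20 were negative under the main scaling, with a median of -0.03, among them the helicase gene MCM4 at 100.2 ± 4.33 and 88.7 ± 2.92 TPM and thymidylate synthase TYMS at 195 ± 10.2 and 179 ± 6.70 TPM. This list's camera adjusted p was 0.000495, and adjusted p = 0.458 with an estimated correlation. Its median was -0.09 to -0.08 under the other scalings, but 0.07 with 23 members positive without ArA replicate 1 and 0.01 with 17 positive without both that library and control replicate 2, where the call was lost (adjusted p = 0.105 and 0.20). Without control replicate 2 or 3 or ArA replicate 2 or 3 it was -0.06, -0.00, -0.06 and -0.08. Less the median of all genes it was -0.09 with all libraries, -0.05 without ArA replicate 1 and -0.06 without both libraries. The 12 tested replication-dependent histone genes, whose transcripts lack poly(A) tails, were listed as a sign of poly(A) selection. They had a median of -0.03 and a camera adjusted p of 0.0260, with adjusted p = 0.253 with an estimated correlation. The list's median less that of all genes was -0.0839, against -0.0850 to -0.0739 under the 3 other scalings. Under each of these the call was lost, at camera adjusted p from 0.0732 to 0.113. It was also lost without control replicate 1 (adjusted p = 0.0502, median 0.01), control replicate 2 (0.644, median -0.00), ArA replicate 2 (0.0795, median 0.02) or ArA replicate 3 (0.349, median -0.00), while the median was -0.08 without control replicate 3 and -0.05 without ArA replicate 1. Less the median of all genes, these 6 values were -0.07, -0.01, -0.02, -0.02, -0.17 and -0.17, against -0.08 with all libraries. H3C2, the histone gene with the smallest p, had 2.01 ± 0.396 and 0.647 ± 0.470 TPM. In the replication and histone lists 0 members passed over all genes and 0 adjusted over the list alone.

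All 15 mitochondrially encoded transcripts, a list fixed as a sign of RNA quality, had negative log2 fold changes under the main scaling. Their median was -0.17, with a camera adjusted p of 1.4e-18, and adjusted p = 0.245 with an estimated correlation. MT-ND6 and MT-ND5, subunits of respiratory complex I, fell adjusted over the list alone, from 4724 ± 213 to 3752 ± 224 TPM and from 3570 ± 175 to 2931 ± 109 TPM (SD, n = 3 each), with 0 past over all genes. Under quantile normalization the list's median log2 fold change was 0.00, and 1 member was positive. Mitochondrially encoded transcripts took 32.9, 32.0 and 31.6% of TPM in control replicates 1, 2 and 3 and 32.1, 28.0 and 26.9% in ArA replicates 1, 2 and 3. The group means were 32.2 ± 0.672% and 29.0 ± 2.75% (SD, n = 3 each), with an exact 2-sided permutation p of 0.3. The median log2 fold change of all tested genes was 0.06, which became 0.01 with median-of-ratios scaling and 0.01 with quantile normalization. It became -0.00206 when TPM were rescaled without mitochondrially encoded genes. Genes with an unadjusted p under 0.05 in limma then split into 152 higher and 124 lower, against 296 and 66 in the main analysis.

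The remaining lists did not pass camera in the main analysis, and 0 of their members passed over all genes or adjusted over the list alone. Camera adjusted p was 0.459 for 22 genes of fatty acid synthesis and desaturation, where the stearoyl-CoA desaturase SCD had 870 ± 59.9 TPM in control and 911 ± 43.3 TPM in ArA libraries (SD, n = 3 each). It was 0.137 for 40 nuclear genes of oxidative phosphorylation, 0.240 for 30 measurements in vesicle and protein secretion, in which VAMP7 is listed under a pair of identifiers, 0.653 for 40 cytosolic ribosomal proteins and 0.803 for 30 genes of MYC and ribosome biogenesis. It was 0.957 for 19 heat shock genes. In 3 lists the median and mean were positive and camera, which compares with all other genes, pointed down: 23 cholesterol synthesis genes (median 0.03, mean 0.02, adjusted p = 0.428), 22 p53 targets (median 0.06, mean 0.05, adjusted p = 0.926) and 4 fibroblast and muscle markers (median 0.02, mean 0.03, adjusted p = 0.719). The medians of the cholesterol and fibroblast lists were negative under each other scaling. Of markers of other cells, only 2 blood cell genes and 4 fibroblast and muscle genes reached the filter on low values, and camera adjusted p was 0.741 for the blood cell genes. For 13 luminal epithelial markers it was 0.0724, with TFF1 at 0.807 ± 0.274 and 2.05 ± 0.342 TPM. Among 23 alternatives, oxidative phosphorylation passed in 5, ribosomal proteins in 4 (3 higher, 1 lower), luminal markers in 3, and cholesterol synthesis and vesicle secretion in 1 each.

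**Figure D2:**
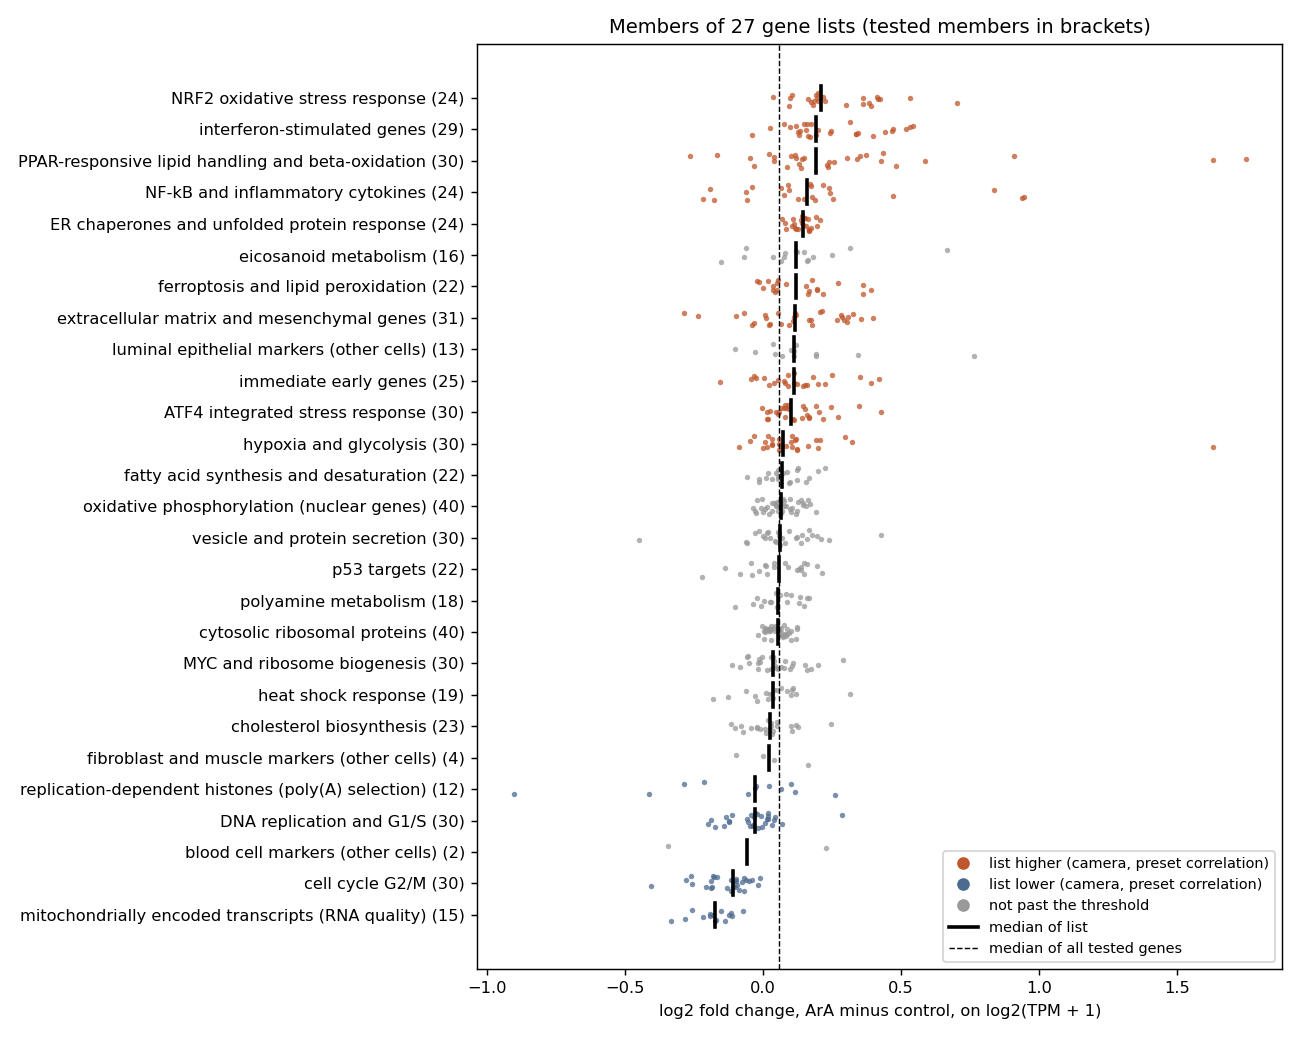
Log2 fold change on log2(TPM + 1), ArA minus control (horizontal axis), of each tested member of 27 gene lists (vertical axis, with the number of tested members); points are genes, colours give the camera call with the preset correlation, black bars are list medians and the dashed line is the median of all tested genes. The median was 0.21 for the NRF2 list, 0.19 for the lipid list and -0.11 for the G2/M list, and 0 of the 27 lists passed with an estimated correlation.

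With the preset correlation 14 of 27 lists passed camera, 10 higher and 4 lower, and none of these calls held with an estimated correlation. The lower lists included the mitochondrially encoded and histone lists, which were fixed as signs of RNA quality and of poly(A) selection. With fry, which tests a list alone and not against other genes, the lipid and NRF2 lists passed, each at adjusted p = 0.0497, and 5 lists passed its test for change in either direction. The positive median of all tested genes, 0.06, therefore counts toward a higher call with fry, which was run under the main scaling only. With both GC correction and an estimated correlation, an alternative added after the data had been seen, the lipid, NRF2 and G2/M lists passed, each at adjusted p = 0.0297.

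Control replicate 2 and ArA replicate 1 stood apart from the other 4 libraries. The first principal component held 41.4% of the variance and placed them at 40.3 and 23.1, against -18.7 to -14.2 for the other 4. They had 20697 and 20645 genes above 0, against 21337 to 22402 in the others. Across genes, which are not independent replicates, their deviation from the gene means had a Spearman correlation with GC content of 0.642 and 0.559, against -0.594 to -0.219 in the others. As each group held 1 of these libraries, each difference was also taken within the pair and within the other 4. The log2 difference of ANGPTL4 was 1.71 within the pair and 1.59 within the other 4 libraries, that of PLIN2 was 0.80 and 0.97, and that of SRM was -0.09 and 0.09. Less the median of all genes, the lipid list's median difference was 0.16 and 0.11, that of NRF2 0.19 and 0.20, that of interferon-stimulated genes 0.24 and 0.11, and that of G2/M genes -0.16 and -0.19. That of mitochondrially encoded transcripts was -0.03 and -0.34. Immediate early genes had 0.00 within the pair and 0.08 within the other 4, hypoxia genes -0.01 and 0.03, ATF4 genes 0.03 and 0.07, and matrix genes 0.09 and 0.06. The ferroptosis list had 0.12 and 0.04, ER chaperones 0.12 and 0.06, NF-kB targets 0.10 and 0.11, DNA replication genes -0.15 and -0.06, and histones -0.13 and -0.07. Without the pair these last 5 lists no longer passed camera, at adjusted p = 0.130, 0.0525, 0.328, 0.20 and 0.130. Their medians over all 6 libraries, less that of all genes, were 0.06, 0.09, 0.10, -0.09 and -0.08, so those of the NF-kB and histone lists differed little between 4 and 6 libraries. With 1 library left out, these medians ranged from 0.03 to 0.10 for the ferroptosis list and from 0.03 to 0.13 for ER chaperones. The ranges were 0.04 to 0.14 for NF-kB targets and -0.12 to -0.05 for DNA replication genes. Without control replicate 2 alone, the ferroptosis, NF-kB and histone lists no longer passed, at camera adjusted p = 0.0836, 0.0570 and 0.644. Their medians less that of all genes were then 0.06, 0.10 and -0.01, so those of the ferroptosis and NF-kB lists changed little. With the pair as a term in limma 5 genes passed: ANGPTL4, PLIN2 and IGF2BP2-AS1 with FABP4 and AQP3. Spearman correlations between libraries over the tested genes ranged from 0.959 to 0.982 within groups and from 0.966 to 0.981 between groups.

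**Figure D3:**
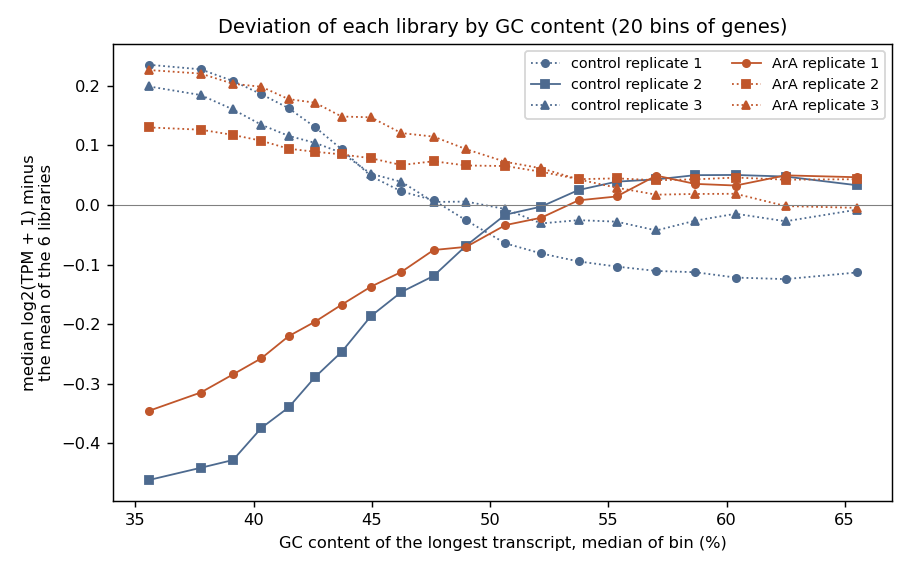
Median deviation of each library's log2(TPM + 1) from the mean of all 6 libraries (vertical axis) in 20 bins of genes by GC content of the longest transcript (horizontal axis, percent); solid lines are control replicate 2 and ArA replicate 1, dotted lines the other 4 libraries, and marker shapes give the replicate number. Genes of low GC content are lower in control replicate 2 and ArA replicate 1 than in the other 4, with a median difference of -0.61 in the lowest bin and 0.07 in the highest.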

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

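The GC correction, the library pair term, the fit without the library pair and the estimated correlation with GC correction were chosen after seeing the data. Against 3 genes in the main analysis (2 higher, 1 lower), 2 passed with median-of-ratios scaling (1 higher), with no filter on low values (1 higher), with eBayes without trend (1 higher) and with a log2 fold change of at least 1 in size, and 2 passed at a mean TPM of at least 5, with 0 lower, since that filter removes IGF2BP2-AS1. Quantile normalization gave 4, and rescaling without mitochondrially encoded genes, pseudocounts of 0.1 and 5 and robust eBayes gave 3 each, the same genes. Array weights gave 214 genes (169 higher, 45 lower), and other splits of the libraries gave up to 5231 with them. The GC correction and the library pair term gave 5 each (4 higher), and leaving out the library pair gave 12 (5 higher, 7 lower). With 1 library left out the count ranged from 0 to 7, higher genes from 0 to 3 and lower genes from 0 to 5; 7 passed without control replicate 2 and 7 without ArA replicate 1. The log2 fold change then ranged from 1.57 to 1.68 for ANGPTL4 (adjusted p 0.0133 to 0.112) and from 0.87 to 0.95 for PLIN2 (0.0445 to 0.476). For IGF2BP2-AS1 the adjusted p then ranged from 0.0129 to 0.0618; as its ArA values are at or near 0, the pseudocount sets its log2 fold change, -5.57 with 0.1 and -1.04 with 5. With the replicate block 0 genes passed in all, 0 higher and 0 lower, and 232 had an unadjusted p under 0.05 in limma; with the block and GC correction 3 passed, 2 of them shared with the main analysis. Same-numbered libraries had correlations of deviations of -0.156, -0.280 and 0.109, not every sample correlated best with its own number, and the numbers were not taken to pair the libraries. The SRM log2 fold change of 0.03 became -0.0222 with median-of-ratios scaling, -0.0309 with quantile normalization, -0.0342 when rescaled without mitochondrially encoded genes, -0.0299 with GC correction and -0.0299 with the replicate block with GC correction, and ranged from -0.0576 to 0.114 with 1 library left out. That of SMS ranged from -0.136 to 0.0767. Apart from the fits with fewer genes or libraries, the cause of these changes was not tested.

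Of 14 lists past camera, 6 kept their call and direction in every alternative at the preset correlation: the lipid, NRF2, ATF4, interferon, G2/M and mitochondrially encoded lists, the last without a value where its genes were removed. The count was 11 to 16 lists under the alternatives of scaling, pseudocount and filter, 12 to 14 with 1 library left out, 10 with array weights, 13 with the replicate block, 13 with GC correction, 15 with the library pair term, 11 without the library pair, 0 with an estimated correlation, 2 with fry and 3 with the estimated correlation with GC correction. The replicate block ended the call of the histone list alone (adjusted p = 0.0581). The ATF4 list kept its call, but its size was not stable. Less the median of all genes, its median was 0.0451 in the main analysis. With 1 library left out it ranged from 0.0076, without ArA replicate 1, to 0.124, without control replicate 2. The cytosolic ribosomal protein list passed as lower without control replicate 1 (adjusted p = 0.0280) and as higher without control replicate 2 (adjusted p = 0.0267) or ArA replicate 1 (adjusted p = 0.00742); with 1 library left out its adjusted p ranged from 0.00742 to 1.00. Robust eBayes leaves camera as it is and was not run for lists. Depth is unknown and limits what can be said of genes near 1 TPM; changes of 0.5 on the log2 scale were mostly missed in simulated data.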

Other observations

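Outside the lists, 8 further genes with low unadjusted p did not pass the adjusted threshold, and all were chosen after their values had been seen. AKR1B1, the aldose reductase gene, had 217 ± 8.76 TPM in control and 305 ± 2.27 TPM in ArA libraries (SD, n = 3 each), a log2 fold change of 0.49 (SE 0.07, limma adjusted p = 0.335). CSF1, the macrophage growth factor gene, had 192 ± 17.9 and 286 ± 13.7 TPM (adjusted p = 0.520). The calcium-binding protein gene S100P had 3.90 ± 0.653 and 8.73 ± 1.76 TPM, the cysteine protease inhibitor gene CST1 7.96 ± 1.23 and 14.2 ± 2.04 TPM, the mucin gene MUC5B 7.28 ± 2.44 and 14.9 ± 2.63 TPM, and the hyaluronan-binding protein gene CEMIP 7.97 ± 0.499 and 13.4 ± 1.66 TPM. FBXO2, which marks glycoproteins for degradation, had 6.68 ± 0.524 and 10.9 ± 0.545 TPM, and ID1, an inhibitor of differentiation factors, 74.4 ± 3.98 and 101 ± 7.96 TPM. Each of these 8 genes was higher in all 3 ArA libraries than in all 3 control libraries. IRF1, an interferon-response factor gene in the NF-kB list, had 12.76, 14.42 and 13.50 TPM in the control libraries and 15.97, 17.42 and 68.12 TPM in ArA replicates 1, 2 and 3. The processed pseudogenes EIF1P3 and DPH3P1 had the opposite direction: EIF1P3 was listed at 2.81, 2.93 and 1.41 TPM in control libraries and at 0 in all 3 ArA libraries, and DPH3P1 at 4.10, 2.08 and 12.21 against 0, 0.72 and 0 TPM; reads of both can be shared with their parent genes.

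The tests of GC content for the library pair, of GC content for the lipid list and of all-or-none values were chosen only after their results or the pattern had been seen; the other tests were set before. The first pattern is that control replicate 2 and ArA replicate 1 stand apart. Across genes, the pair's log2 deviation had a Spearman correlation with GC content of 0.689, which is consistent with a GC content bias between libraries as part of the separation. After GC correction the first principal component (29.9% of the variance) still placed the pair at 29.1 and 13.9, against -14.9 to -1.89 for the other 4, so the fitted GC trend is not all that sets them apart. Lower depth alone would give a weaker relation where counting noise is small, and transcript length alone none once length is removed, yet the correlation was 0.715 among 2233 genes with a mean of at least 50 TPM and 0.673 after the part due to length had been removed. No biological explanation was tested, as the design names none for this pair, and a shared batch of preparation stays open because the labels give none.

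The second pattern is the higher lipid-handling list and the lower G2/M list in ArA libraries. After GC correction the lipid list's median log2 fold change less that of all genes was 0.135, against 0.133 before. The bootstrap interval of the change on correction was -0.0155 to 0.0235. The bootstrap resampled list members and kept the 6 libraries fixed. Its intervals here give the spread between genes and not between libraries. The lipid list's members had a median GC content of 48.7%, against 48.3% for all genes. A list this close to all genes in GC content can hardly move on correction, so this test cannot decide on GC content bias. The bound first written for this test, that the corrected list's own interval should exclude 0.5 of the uncorrected value (0.0667), was not met, because that interval started at 0.0559, and the paired bound replaced it after that had been seen. A smaller mitochondrial share would raise all other genes alike, whereas the lipid list lay 0.134 above the median of all tested genes (interval over list members 0.0618 to 0.267). With 1 library left out, this value ranged from 0.111 to 0.175. For the G2/M list the value after GC correction was -0.162, against -0.167 before. Its interval of -0.222 to -0.143 excluded 0.5 of the uncorrected value (-0.0833). With 1 library left out and no GC correction, the value ranged more widely, from -0.288 to -0.134. Control replicate 2 and ArA replicate 1 lay in opposite groups, so the fitted trends largely cancelled and could move this list little. The fitted trend thus accounts for little of the difference, and GC effects outside it were not tested. The ArA treatment, the difference the design names, stays open and was not tested apart from the comparison itself. Of the 10 splits of the 6 libraries into 3 and 3, the real split called 14 lists and each other split 1 to 8, so that 1 split gave as many. Splits that mix the groups thus also gave list calls at the preset correlation. For single genes 2 of the 10 splits gave as many as the real 3, the highest other also calling 3. The other such split set control replicates 1 and 2 with ArA replicate 1 against the rest, which keeps the library pair together. With the pair as a term 5 genes passed, but that term was fitted to the real split only and cannot weigh between splits. With 10 splits no share under 0.05 can be reached for either count of calls. At an unadjusted p under 0.05 in limma the real split had 362 genes. The splits that keep control replicate 2 and ArA replicate 1 together had more, at 1475, 1117, 2568 and 1751 genes. The other splits that part these libraries had 110 to 268.

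The third pattern is IGF2BP2-AS1, listed near 0 in all 3 ArA libraries. Fewer reads from the overlapping gene IGF2BP2 would need that gene to be lower by at least 1 on the log2 scale, whereas its log2 fold change was 0.419 (95% interval -0.220 to 1.06). All-or-none values that any split gives may account for it: 6 genes lay at 1 TPM or more in 3 libraries and at 0.05 TPM or less in the other 3 by group, and another split of the libraries gave 8. The splits with 8 and 7 such genes keep control replicate 2 and ArA replicate 1 together, and the other splits that part this pair, as the real one does, gave 2 to 5. A failed estimate for this transcript in a TPM table, and a change in its transcription after ArA, both stay open.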
